A study of Mus musculus with 6 samples.

How the data were processed

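Gene expression was measured in a mouse glioblastoma stem cell line on 6 one-colour Agilent arrays, 3 from cells carrying a non-target control hairpin and 3 from cells carrying a hairpin against Ggct. Per the labels, the line was grown as neurospheres in serum-free medium with EGF and bFGF, both hairpins were delivered by lentivirus, and Cy3-labelled cRNA was hybridised. The group of each array was taken from its title, and the replicate number from the order of the dates that open the titles. Each of the 3 dates was shared by 1 control and 1 knockdown array, so the labels mark a shared day. The main fit did not use these 3 pairs. They served for differences per pair and for a block tried as an alternative. As a check of the pairing, the deviations of the paired arrays from their group means correlated across genes at -0.02, 0.55 and -0.20 for pairs 1, 2 and 3. The labels do not say whether samples of a group were separate cultures beyond those dates, so p-values measure the spread between these arrays, part of which could be technical.

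The scanner files hold spot intensity values on a linear scale that Agilent Feature Extraction 11.0.1.1 had corrected for background, per the file headers. The background subtraction and spot flags are the authors' scanner output and were kept as deposited. The deposited value table of the series holds log2 values, and its processing was worked out by comparison with the scanner files. In each column every compared probe differed from log2 of the processed signal by 1 constant (9.05 to 9.75 log2 units) within a tolerance of 0.01, with the 75th percentile of the column at about 0 and no centring of genes. The column medians of that table ran from -4.47 to -4.22. All 6 arrays carried the same scan date, so the scan date could not act as a batch. The slide and the position of an array on it were not compared.

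Spots flagged as outliers were left out, and the spots of a probe were averaged as log2 intensities. 56605 non-control probes were read, and 12 were left out because every spot was an outlier on some array. The log2 processed signal minus the 75th percentile of the same array, taken over probes after averaging, was the value analysed. Arrays had 54.5% to 56.8% of their probes well above background, the 75th percentile of the signal over spots, repeated ones included, ran from 812 to 1373 intensity units, and 0 probes were saturated. The number of arrays limits the precision. The probes' accessions were matched without version to a RefSeq gene table of mouse assembly GRCm38, which named 32994 probes, or 58.3%, and left 23611 unnamed. The table was used for names only, since the build of the array design differs, and no coordinates are given. Probes well above background on at least 3 of the 6 arrays were kept, 31804 in all, of which 20917 were named. For each of the 14151 genes the probe with the highest mean over all 6 arrays was used.

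Knockdown was compared with control by limma 3.58.1 in R 4.3.3 with lmFit and eBayes, two-sided, without a block, and p-values were adjusted by the Benjamini-Hochberg method over the 14151 genes. The threshold was an adjusted p below 0.05. Log2 fold changes are knockdown minus control and are given with their standard error (SE). 22 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Python 3.11.15 with pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the plots. The test, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule took Ggct, Notch1 and Jun, then the 10 largest rises and 10 largest falls among genes past the threshold. Those genes had to be well above background on all 6 arrays, to change the same way in all 3 pairs and to have a symbol that is not a clone, locus or predicted gene. It also took up to 3 genes per direction that were above background in 1 group only, and up to 4 members of each list past the threshold. Where a count of list members was 5 or fewer, members beyond that rule are also named, chosen after their values were seen. Results of 2 single genes are not reported here.

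A gene on no array above background in 1 group has only a lower bound on its fold. It was computed as the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. On simulated arrays with the genes' own means and spreads, 200 of 14151 genes were changed in each of 20 runs of the knockdown against control comparison. The fit recovered 15.1% of the genes changed 1.5-fold, 60.7% of those changed 2-fold and 89.3% of those changed 4-fold, and 5.3% of its calls were false. These rates hold for genes drawn independently with 200 changed, whereas 1048 genes passed in the data. They are therefore not the recovery or the false share of the real comparison. In the same simulations, with genes drawn independently, camera called 0.05 lists per run where nothing had been changed. Correlations estimated for the lists in the data ran from -0.10 to 0.50. The simulated rate of list calls therefore does not show how often camera calls unchanged lists here.

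The alternatives tried were quantile normalization, normexp background correction with quantile normalization, the 75th percentile over probes above background on all arrays, median centring, the deposited values, a filter on all 6 arrays, no filter, the mean of a gene's probes, an intensity trend with robust variance, the pair as a replicate block, array weights and each array left out in turn. Further ones were testing all probes, camera with an estimated correlation and fry. Normexp added an offset of 50 intensity units before the logarithm, which by itself shrinks the folds of dim genes. Leaving out pair 1 as a whole was added after seeing the data.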

Results

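Total RNA of a mouse glioblastoma stem cell line was profiled on 6 one-colour arrays, 3 of cells transduced with a non-target hairpin (control) and 3 of cells with a hairpin against Ggct (knockdown). The line grows as neurospheres and came from mouse brain tumours induced with a transposon. Ggct encodes gamma-glutamylcyclotransferase, an enzyme of the gamma-glutamyl cycle that breaks down glutathione products. The design asks how gene expression changes when Ggct is suppressed, and the title of the series names Notch1 and c-Jun. The titles of the 3 knockdown samples name 1 hairpin, so an effect of that hairpin other than loss of Ggct is not separated here.

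Ggct fell to 12.7% of control in the knockdown, a log2 fold change of -2.97 ± 0.20 (SE; limma adjusted p = 0.00314). Its normalised log2 signal was 3.58 ± 0.23 (SD, n = 3) in control and 0.61 ± 0.35 (SD, n = 3) in knockdown arrays, and the 3 pairs differed by -3.10, -2.82 and -3.00. Notch1, a receptor of the Notch pathway, did not differ beyond the spread between arrays. Its log2 fold change was 0.09 ± 0.22 (SE; limma adjusted p = 0.851), with a 95% interval from -0.43 to 0.61 that allows a fall of up to 25.7% in its mRNA, and its signal lay at least 3.25 log2 units above the lowest signal well above background. The pairs disagreed in direction, with Notch1 differences of -0.32, -0.01 and 0.60. Jun, which encodes the AP-1 transcription factor c-Jun, had a log2 fold change of -0.36 ± 0.26 (SE, limma adjusted p = 0.433) with a 95% interval from -0.96 to 0.23. Its pair differences were all below 0, at -0.80, -0.22 and -0.07, and Jun did not pass with the replicate block (limma adjusted p = 0.2945).

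**Figure D1:**
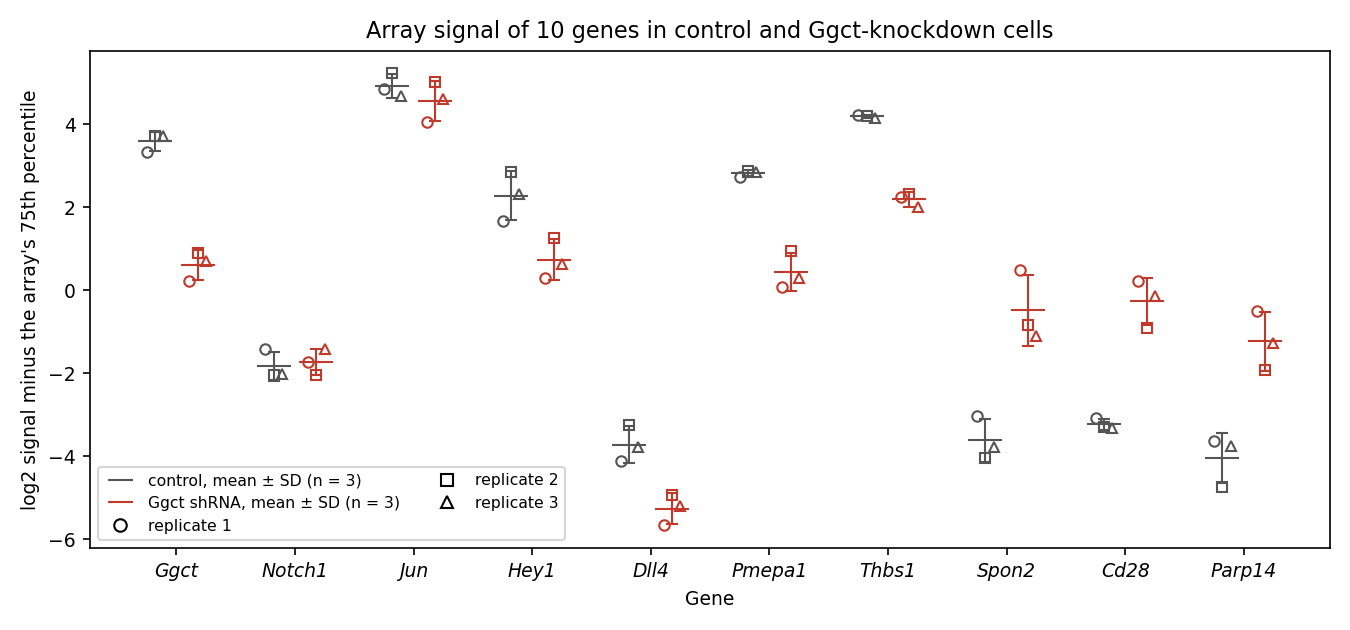
Normalised log2 signal (log2 signal minus the 75th percentile of the array, vertical axis) of 10 genes in control arrays (grey) and knockdown arrays (red), with 1 symbol per replicate and the mean ± SD of each group. Ggct lies at a mean of 3.58 in control and 0.61 in knockdown arrays, while the Notch1 means are -1.83 and -1.73.

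Of 14151 genes tested, 1048 passed the threshold, 646 higher and 402 lower in the knockdown, and 3507 had an unadjusted p below 0.05. Of these, 360 had changed at least 2-fold, 275 higher and 85 lower. In all 3 pairs, 187 genes differed at least 2-fold in the same direction, 149 higher and 38 lower. With the sign of any single pair turned, 1 gene did. Turning a pair also removes every gene that changed alike in all pairs, so that low count follows in large part from the design. It is not a null for the 187, and this count was not among those set beforehand. With the pair as a replicate block, 558 genes passed, 394 higher and 164 lower, of which 487 were among the 1048. The count fell when single arrays were left out. It was 14 without control replicate 1, 42 without control replicate 2 and 21 without knockdown replicate 3. Without control replicate 3 it was 424, and without knockdown replicate 2 it was 626. With single arrays left out, 2581 to 3353 genes still had an unadjusted limma p below 0.05, and the cause of the lower counts was not tested. Knockdown replicate 1 stood apart from the other arrays on the first principal component, at 46.6 against 9.1 and 15.4 for the other knockdown arrays, and 840 genes passed without it.

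The 10 largest rises included 3 genes of the interferon response. Spon2, which encodes a secreted matrix protein, rose 8.73-fold (log2 fold change 3.13 ± 0.43, SE; limma adjusted p = 0.0135), and Cd28, a costimulatory receptor of T cells, rose 7.79-fold (2.96 ± 0.27, SE; limma adjusted p = 0.00607). Agt, the angiotensin precursor made by astrocytes in brain, rose 6.41-fold. Rgs8, a regulator of G-protein signalling, rose 5.31-fold (log2 fold change 1.78 with the mean of its probes, the second of which was at 1.16), and the orphan receptor gene Gpr146 rose 5.11-fold. Thrsp, a gene linked to lipid synthesis, rose 4.89-fold and Tmem140 4.58-fold. The interferon-induced genes Parp14, Oasl2 and Rsad2 rose 7.04-fold, 5.18-fold and 5.04-fold. All 10 were higher in all 3 pairs and above background on all 6 arrays, and all 10 passed with the replicate block. With normexp the folds of 7 of them were more than 1.5 times smaller, such as 2.97-fold for Parp14 and 2.88-fold for Agt. The offset added in normexp shrinks the folds of dim genes by itself. Without knockdown replicate 1, Agt was 3.97-fold and Rsad2 3.05-fold higher. In limma, Agt did not pass with normexp (adjusted p = 0.0602) or without a filter (0.0682), nor Rsad2 with normexp (0.0562), quantile normalization (0.063) or without a filter (0.0981), nor Thrsp without a filter (0.074) or without pair 1.

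The largest falls were in genes of varied function. Pmepa1, a TGF-beta target that limits the pathway, was 5.20-fold lower (log2 fold change -2.38 ± 0.22, SE; limma adjusted p = 0.00631). Thbs1, which encodes the matrix protein thrombospondin-1, fell to 25.0% of control (limma adjusted p = 0.00314). Grem1, a secreted antagonist of BMP ligands, was 3.33-fold lower with an adjusted p of 0.0448 that was 0.0645 with the replicate block. Nppb, encoding a natriuretic peptide, was 3.65-fold lower, the small GTPase gene Rab15 3.54-fold, the desmosome gene Pkp1 3.29-fold, Entpd5 3.27-fold and the semaphorin gene Sema7a 3.12-fold. Hivep3, a zinc finger gene, was 3.20-fold lower, with an adjusted p of 0.0265 that was 0.0546 with the replicate block. Grem1 also did not pass with quantile normalization, with the 75th percentile over probes above background on all arrays, without a filter or without pair 1, and Hivep3 did not pass without a filter and had a log2 fold change of -0.79 with normexp.

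Some genes were well above background on all arrays of 1 group and on none of the other, 45 in the knockdown alone and 8 in the control alone, of which 32 and 6 passed the threshold. Cldn2, a tight junction gene, was at least 4.96-fold higher in the knockdown, Sectm1a at least 4.3-fold and Gbp6, an interferon-inducible GTPase gene, at least 3.35-fold. Grm6, a glutamate receptor gene, was at least 1.96-fold lower, Dlgap1 at least 1.61-fold and Spef2 at least 1.56-fold.

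The interferon response list moved furthest of the 22 lists. Of its 35 tested members, 21 rose, 0 fell and 14 did not pass, and the median log2 fold change was 1.04 (camera adjusted p = 1.76e-16; adjusted p = 0.492 with an estimated correlation). The median was 0.91 with Psmb9, which was above background in the knockdown only, set to its bound of 1.49-fold. Parp14, Oasl2, Rsad2 and Xaf1, a gene of apoptosis induced by interferon, led the members past the threshold, with Xaf1 4.24-fold higher. A second Xaf1 probe had a log2 fold change of -0.09, so its probes disagreed. 26 members passed adjusted over the list alone, all higher, and with the replicate block 21 passed. 31 of the 35 members were higher in all 3 pairs, and without knockdown replicate 1 the median was 0.83 with 19 members past the threshold.

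**Figure D2:**
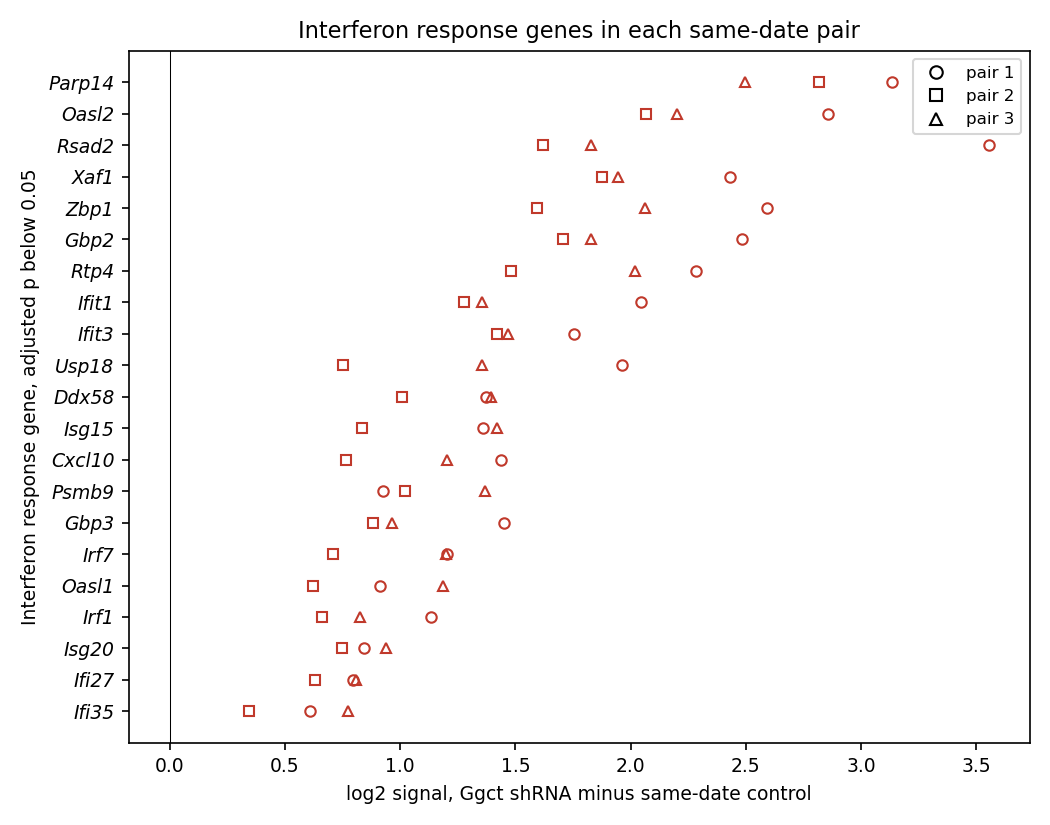
Log2 difference between knockdown and control in each pair (horizontal axis, 1 symbol per pair) for the 21 members of the interferon response list with an adjusted p below 0.05 (vertical axis). All 21 lie above 0 in all 3 pairs, and Psmb9 is drawn at its measured signal although it was below background in control arrays.

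Single genes of the Notch lists passed, and neither list was called as a whole. Of 25 Notch components, Psenen, a subunit of gamma-secretase, rose 1.41-fold, and the ligand gene Dll4 and the receptor gene Notch4 fell, with log2 fold changes of -1.54 ± 0.26 and -0.70 ± 0.13 (SE). Dll4 was above background on all 3 control arrays and on 1 knockdown array. The list's median was -0.04 (camera adjusted p = 0.613), and with the replicate block 0 members were higher and 1, Dll4, lower past the threshold. Of 7 tested genes in the list of Notch targets, Hey1, a repressor induced by Notch, was 2.92-fold lower (-1.54 ± 0.33, SE; limma adjusted p = 0.0374). Hes6, which antagonises Hes1, rose 1.80-fold. Hes6 was in the list as set beforehand, and because it opposes Hes1 its rise is not read as induction of Notch targets. The median of the 7 was -0.002 (camera adjusted p = 0.613), with pair medians of -0.158, -0.125 and -0.178. Without knockdown replicate 1 the median was -0.154 and Hey1 did not pass. The other members of this list of 12, Hes5, Hey2, Heyl, Nrarp and Dtx1, were above background on too few arrays to be tested. With them missing, the median does not settle whether Notch targets moved together. Adjusted over the list alone, 2 components were higher and 2 lower, Lfng (0.93) being the addition. In the target list 1 member, Hes6, was higher and 2 lower, Hey1 and, as the addition, Hes1 (-0.41).

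A minority of AP-1 and growth factor response genes passed, most of them lower. In the AP-1 family, to which c-Jun belongs, 0 of 14 tested members rose and 2 fell, Jdp2 (-0.64 ± 0.11, SE) and Mafk (-0.49 ± 0.11, SE), and neither passed with the replicate block. The median was -0.40 (camera adjusted p = 0.00585; adjusted p = 0.492 with an estimated correlation), and 3 members fell adjusted over the list alone, Fosl1 (-0.71) being the third. Without knockdown replicate 1 the AP-1 median was -0.241, and the pair medians were -0.502, -0.288 and -0.205. Of 27 genes of MAPK feedback and immediate response, 5 fell and 1 rose, with a median of -0.24 (camera adjusted p = 0.00265; adjusted p = 0.559 with an estimated correlation). Another split of the 6 arrays, holding both groups on each side, gave this list a median 0.99 times the size. Among splits that part all 3 pairs the highest was 0.45 times. The falls were the EGF receptor ligand genes Areg (-1.58 ± 0.27, SE) and Hbegf (-1.26 ± 0.15, SE), the immediate early genes Egr3 (-1.41 ± 0.20, SE) and Egr1 (-0.76 ± 0.18, SE), and Spred2 (-0.65), and the rise was Etv1 (0.63). 8 fell and 1 rose adjusted over the list alone, and with the replicate block 4 fell and 0 rose.

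A minority of glutathione genes passed, most of them higher. Of 35 tested members of glutathione metabolism, 8 rose and 1 fell, with a median of 0.23 (camera adjusted p = 0.0035; adjusted p = 0.492 with an estimated correlation). The 8 rises were all glutathione S-transferase genes, cytosolic or microsomal, such as Gsta4 (2.46-fold), Gstt1 (2.13-fold) and Mgst1 (1.80-fold, block adjusted p = 0.067), and probes of close paralogs in this family can cross-hybridise. That grouping was made after the values were seen, and other transferase genes of the list, such as Gstp1 and Gstz1, did not pass. The fall was Chac1, which encodes an enzyme that degrades glutathione, at -1.49 ± 0.32 (SE; limma adjusted p = 0.0358, or 0.0624 with the replicate block). 11 rose and 1 fell adjusted over the list alone, and with the replicate block 5 rose and 0 fell. Of 26 NRF2 targets, an oxidative stress programme, 0 rose and 2 fell, Abcc4 (-0.66) and Me1 (-0.52), with a median of -0.01 (camera adjusted p = 0.727). Both falls were the same adjusted over the list alone, and 0 passed with the replicate block.

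A minority of ATF4 and cholesterol genes passed, most of them lower. Of 34 tested genes of ATF4 and the integrated stress response, 5 fell and 1 rose, with a median of -0.27 (camera adjusted p = 9.22e-06; adjusted p = 0.555 with an estimated correlation). Another split of the 6 arrays, holding both groups on each side, gave this list a median 1.12 times the size. Among splits that part all 3 pairs the highest was 0.61 times. The pair medians were -0.565, -0.245 and -0.096, and without knockdown replicate 1 the falls were 3. Besides Chac1, the falls were the proline synthesis gene Aldh18a1 (-0.79), Stc2 (-0.72), Vldlr (-0.69) and the mitochondrial folate enzyme gene Mthfd2 (-0.62), and the rise was Ddit4 (1.20), an inhibitor of mTORC1. Adjusted over the list alone, 8 fell and 1 rose, and with the replicate block 1 fell and 1 rose. Of 23 cholesterol synthesis genes, 4 fell and 0 rose, among them Hsd17b7 (-1.62 ± 0.32, SE), Dhcr7 (-0.77 ± 0.15, SE) and the regulator gene Srebf2 (-0.67). The median was -0.25 (camera adjusted p = 7.96e-05; adjusted p = 0.492 with an estimated correlation), 10 fell adjusted over the list alone and 2 with the replicate block.

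Few cell-cycle genes passed, all of them lower. Of 54 genes of G1/S and DNA replication, Brca2 (-0.71 ± 0.15, SE) and Chaf1a (-0.60 ± 0.14, SE) fell and 0 rose, with a median of -0.13 (camera adjusted p = 0.00118; adjusted p = 0.584 with an estimated correlation). Of 61 genes of G2/M and mitosis, Foxm1, a transcription factor of mitotic genes, fell (-0.51 ± 0.11, SE), 0 rose, and the median was -0.18 (camera adjusted p = 2.67e-05; adjusted p = 0.584 with an estimated correlation). In both lists 0 members passed adjusted over the list alone or with the replicate block, and without knockdown replicate 1 the falls were 1 and 0. None of the 7 CDK inhibitor genes passed in limma over all genes or adjusted over the list alone. All 7 had values above 0, with a median of 0.31 (camera adjusted p = 0.0599, or 0.0488 with the replicate block; adjusted p = 0.492 with an estimated correlation).

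Of 25 tested p53 targets, 7 rose and 1, Zmat3 (-0.96), fell, without a shift of the list (median 0.04, camera adjusted p = 0.408). The rises included Trp53inp1 (4.03-fold, with a second probe at a log2 fold change of 1.004), the antiproliferative gene Btg2 (2.41-fold), the stress-response gene Sesn1 (2.30-fold) and the pro-apoptotic Bbc3 (2.02-fold). 8 rose and 3 fell adjusted over the list alone, and with the replicate block 4 rose and 2 fell, leaving out Btg2, Sesn1 and Ddit4l. Of 35 hypoxia and glycolysis genes, Ndrg1 (-1.27), Vegfa (-1.09) and the glucose transporter gene Slc2a1 (-0.58) fell and Bnip3l (0.63) rose. Their median was -0.01 (camera adjusted p = 0.408), with the same counts adjusted over the list alone and 1 fall, Vegfa, with the replicate block.

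**Figure D3:**
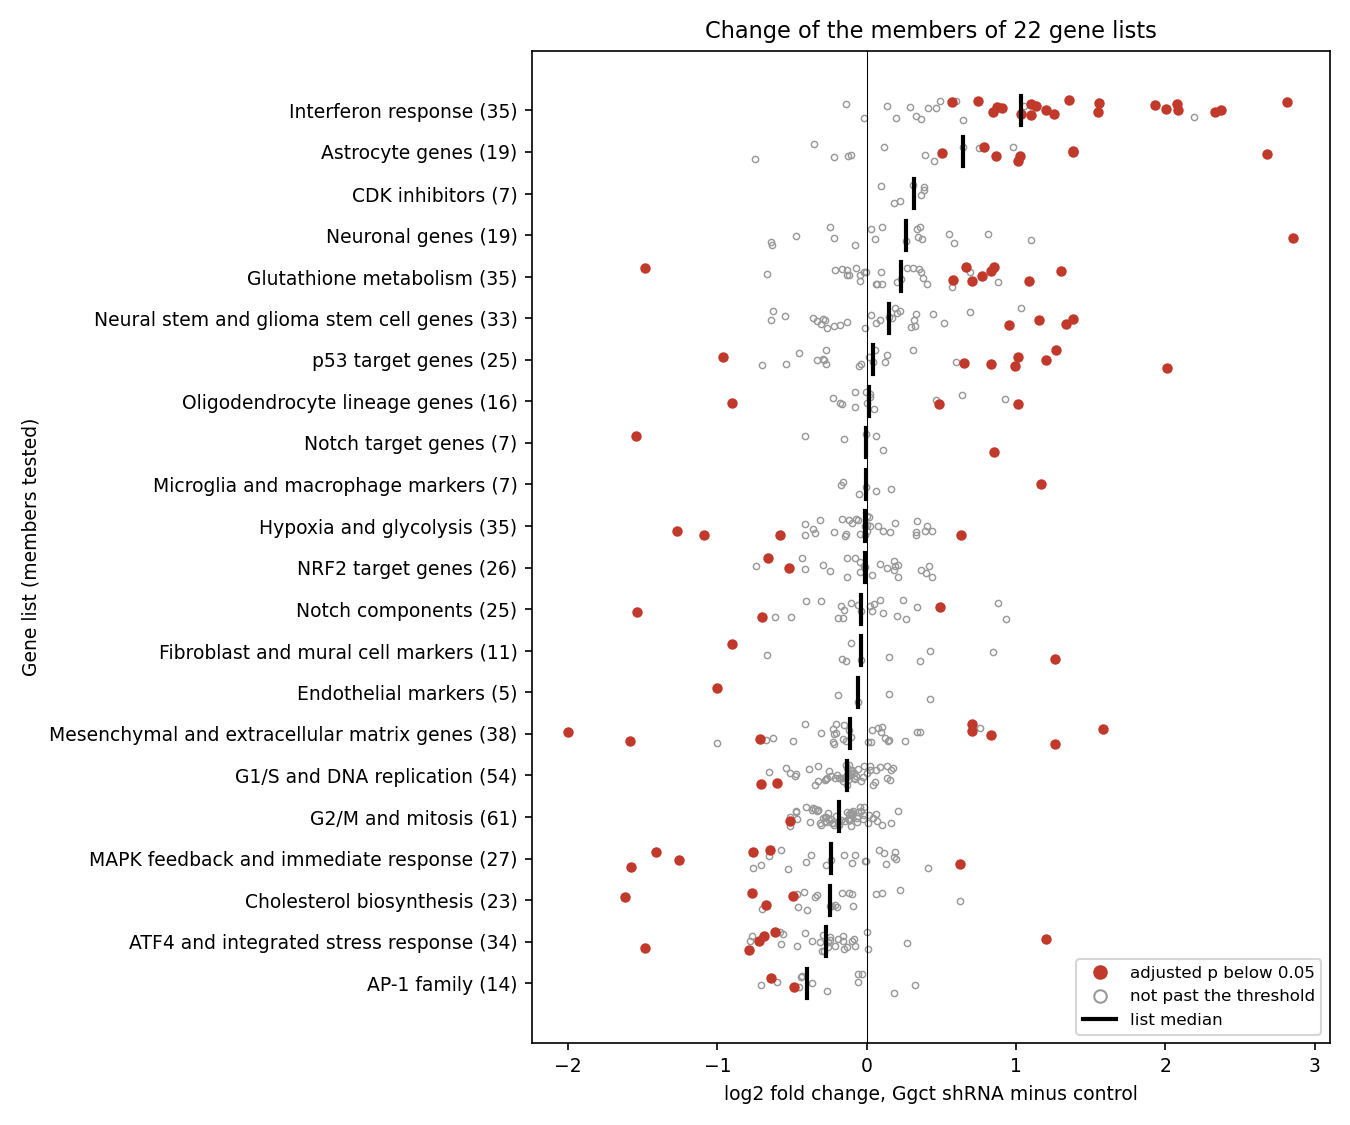
Log2 fold change, knockdown minus control (horizontal axis), of each tested member of the 22 gene lists (vertical axis), red where the adjusted p was below 0.05, with the list median as a black line. Medians run from -0.40 for the AP-1 family to 1.04 for the interferon response, and points of genes below background in 1 group are fitted values.

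The astrocyte genes that passed were all higher. Of 19 tested, 8 rose and 0 fell, with a median of 0.65 (camera adjusted p = 0.00012; adjusted p = 0.492 with an estimated correlation). Agt led the list, followed by Id3 (1.38 ± 0.22, SE), Cbs, an enzyme of cysteine synthesis (1.38 ± 0.14, SE), and Clu, which encodes clusterin (1.03 ± 0.15, SE). 11 rose adjusted over the list alone, and with the replicate block 5 rose. Of 33 neural and glioma stem cell genes, 4 rose and 0 fell, Id3, the surface marker gene Cd24a (1.33), Id2 (1.15) and the chemokine receptor gene Cxcr4 (0.95), with a median of 0.15 (camera adjusted p = 0.391). Adjusted over the list alone 5 rose, and with the replicate block 3 rose, leaving out Id2. Of 19 neuronal genes, 1 rose, Stmn3, at least 2.55-fold higher, with a median of 0.26 (camera adjusted p = 0.391) and 3 higher and 1 lower adjusted over the list alone. Of 16 oligodendrocyte lineage genes, the myelin genes Mbp (1.01) and Cnp (0.48) rose and the progenitor receptor gene Pdgfra (-0.90) fell, with a median of 0.01 (camera adjusted p = 0.613), and Cnp did not pass with the replicate block. In this list 4 rose and 1 fell adjusted over the list alone, and 1 rose and 1 fell without knockdown replicate 1.

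Mesenchymal and matrix genes moved both ways. Of 38 tested, 5 rose, Tgfbi (1.58 ± 0.28, SE), Col1a2 (1.26 ± 0.19, SE), Mmp2 (0.83), S100a4 (0.71) and Col5a2 (0.71), and 3 fell, Thbs1, Ccn1 (-1.58 ± 0.17, SE) and Plaur (-0.71). The median was -0.11 (camera adjusted p = 0.408), with 5 higher and 5 lower adjusted over the list alone and 3 higher and 4 lower with the replicate block. Without knockdown replicate 1, 3 rose and 3 fell. Markers of other cell types did not shift as lists. Of 7 tested microglia and macrophage markers, 1 rose, Tmem119 (1.17), with a median of -0.003, although their mean was 0.14 and the test pointed up (camera adjusted p = 0.695). Of 5 endothelial markers, 1 fell, Flt1, to 49.9% of control (limma adjusted p = 0.0187, or 0.0527 with the replicate block), with a list median of -0.06 (camera adjusted p = 0.646). Of 11 fibroblast and mural markers, Col1a2 rose and Pdgfra fell, with a median of -0.04 against a mean of 0.09 and a test that pointed up (camera adjusted p = 0.912). Adjusted over the list alone these 3 lists had 1, 1 and 2 members higher and 0, 1 and 1 lower.

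Camera called 9 of the 22 lists at the preset correlation. With a correlation estimated for each list it called 0, with 1 list, the astrocyte genes, at an unadjusted p below 0.05 (0.0487), and fry called 3, the interferon, astrocyte and glutathione lists, each with an adjusted p of 0.0321.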

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

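The tests in this part that concern interferon genes were chosen after their rise had been seen. Probes without a gene name in the table used here were outside the comparison of genes. Of 10887 such probes tested in a limma fit of all probes, 137 passed the threshold, and 59 of them were at least 2-fold higher in the knockdown than in the controls, against 32 at least 2-fold lower. The one with the smallest adjusted p had a log2 fold change of 3.29 ± 0.22 (SE; limma adjusted p = 0.0147). Which genes these probes report stays open.

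The rise of interferon genes, with a median log2 fold change of 1.04, was weighed against 3 explanations. A single divergent knockdown array would leave no rise once removed, but without knockdown replicate 1 the list's median was 0.833, and it was 0.747 and 0.964 in pairs 2 and 3. Immune cells in the knockdown cultures would bring their abundant transcripts, but the tested microglia and macrophage markers had a median of -0.003 (SD 0.467 over 7 genes), and 11 of the 12 other markers, among them Ptprc, Lyz2 and Aif1, were above background on no array. A response to this hairpin other than through loss of Ggct cannot be told apart here, because the arrays hold 1 Ggct hairpin and a second would be needed. Both groups received a hairpin by lentivirus, so a response common to both would not show as a difference. An effect of Ggct loss therefore remains an untested biological explanation.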

How the results depend on the processing

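The planned normexp setting on mean spot signals was not run because the scanner files used here hold the median signals, which took its place, chosen after seeing the data as was leaving out pair 1. Under 18 alternatives Ggct stayed past the threshold, with log2 fold changes from -3.12 to -2.78 and limma adjusted p from 0.000148 to 0.0291, and Jun stayed below 0 and not past it (-0.59 to -0.11, adjusted p 0.205 to 0.782). Notch1 never passed (adjusted p 0.5 to 0.996), and its sign turned without control replicate 2 (-0.0151), control replicate 3 (-0.0026) and knockdown replicate 3 (-0.0683), with a range from -0.0683 to 0.294 over the arrays left out.

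The 1048 genes became 678 with median centring, 357 without a filter, 556 over all probes, 558 with the replicate block, 2559 with array weights and 343 without pair 1, and 14 to 840 with single arrays left out, where 2581 to 3353 genes still had an unadjusted p below 0.05. The 360 genes changed at least 2-fold became 164 with normexp, 229 without pair 1, and 14 to 390 with single arrays left out. The offset added in normexp shrinks folds of dim genes by itself, but its share in the fall to 164 was not measured. The cause of the other changes was not tested. None of the 76 other genes picked by rule turned direction under any alternative, and of these 51 kept their call with the replicate block, 40 without a filter and 5, 11 and 7 without control replicate 1, control replicate 2 and knockdown replicate 3. A further 67 genes were followed, the remaining list and group members past the threshold plus Gbp10, Ereg, Egf, Lfng, Hes1 and Fosl1. Of these 67 genes 0 turned direction, and of their 1200 values under the alternatives 828 kept the call and 358 lost it. Nearly all genes of both sets were picked for passing the threshold, so a kept direction was likely beforehand. The replicate block changed no call of Ggct, Notch1, Jun or a list other than the CDK inhibitors.

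Camera called 9 or 10 lists under each of the 18 alternatives, the same 9 each time, and 9 to 10 with single arrays left out. The list added in 5 of the 18 was the CDK inhibitors (camera adjusted p from 0.0226 to 0.141 over the 18). Camera called 0 with an estimated correlation and fry called 3, and the cause was not tested. For 4 lists that were not called the test turned direction, though the medians given here did not always change sign. NRF2 target genes turned without control replicate 2 (0.0397; -0.0343 to 0.057 with single arrays left out), and Microglia and macrophage markers without a filter (-0.0315). Endothelial markers turned without a filter (-0.032), without control replicate 1 (0.0591; -0.126 to 0.0591 with single arrays left out) and without pair 1 (0.0705). Fibroblast and mural cell markers turned with normexp (-0.0624), quantile normalization (-0.0479), the mean of probes (-0.107), without control replicate 1 (-0.0066), without knockdown replicate 3 (-0.0112) and without pair 1 (-0.001), and ran from -0.0112 to 0.149 with single arrays left out. The cause was not tested. Signal over background limits the genes seen in 1 group only, whose folds are bounds.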

Other observations

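The gene groups and tests in this part were all chosen after the values had been seen, including the counts over other splits. Interferon-inducible GTPases act against intracellular pathogens. Of 17 genes in the group 12 were tested, and of these 11 rose and 0 fell. The rises included Ifi47 (2.03 ± 0.19 log2, SE; limma adjusted p = 0.00741), Igtp (1.51 ± 0.21, SE) and Tgtp2 (2.18 ± 0.30, SE, above background on 2 of 3 control arrays). Gbp10 (0.43 ± 0.15, SE) did not pass. Gbp6, Gbp9 and Gbp4 were on no control array above background and were at least 3.35-fold, 2.09-fold and 1.89-fold higher. They met the filter through the knockdown arrays alone, which favours genes that rose, so the share of rises in the group is raised by the filter. With such genes at their bound the group's median was 1.33. Its members Gbp2 and Gbp3 were also in the interferon list, and no p-value is given for this or the other groups as a whole because they were put together after their genes had been seen. Of 15 tested genes of class I antigen presentation, 7 rose and 0 fell, among them Tapbp (1.21 ± 0.21, SE) and H2-M3 (1.12 ± 0.17, SE), with 6 past the threshold with the replicate block and 5 without knockdown replicate 1. B2m and Psmb9 of this group were also in the interferon list, and Psmb9 was on no control array above background, so it too met the filter through the knockdown arrays alone. Ifnb1, Ifna4 and Ifng were above background on no array. Of 9 tested interferon receptors and sensors, 1 rose, Ifngr2 (0.60 ± 0.14, SE; adjusted p = 0.0478, or 0.105 with the replicate block). This group left out sensor genes that are in the interferon list. Of those, Ddx58 (1.26, limma adjusted p = 0.0149) and Zbp1 (2.08, limma adjusted p = 0.00768) rose, and Ifih1 (0.49) and Dhx58 (0.60) did not pass. Of 5 tested T cell markers 0 passed, with a median of 0.01, while Cd28 rose 7.79-fold.

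The medium held EGF. Of 6 tested ligands of the EGF receptor family, 4 fell (3 with the replicate block), Areg, Btc (-1.47 ± 0.19, SE), Hbegf and Nrg1 (-0.81 ± 0.15, SE; adjusted p = 0.0233, or 0.0585 with the replicate block). Ereg (-0.65 ± 0.17, SE) and Egf (0.46 ± 0.23, SE) did not pass. The group's median was -1.04, and 3 of its members were also in the MAPK list.

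FoxO transcription factors switch on a set of genes when PI3K and Akt signalling is low. Of 28 tested genes known to respond to FoxO, 9 rose and 0 fell, led by Pik3ip1, an inhibitor of PI3K (2.03 ± 0.12 log2, SE; limma adjusted p = 0.00314), Trp53inp1 (2.01 ± 0.31, SE, with a second probe at 1.004), Fbxo32 (1.98 ± 0.31, SE), Mxd4 and Txnip, and 6 passed with the replicate block. 4 of the 28 were also in the p53 list. The 19 members not past the threshold had a median of 0.209, with 14 of them above 0. Among the 19, Irs2 (0.001), Cdkn1b (0.10) and Bcl2l11 (0.09) were close to unchanged. Tnfrsf10b (-0.54), Insr (-0.47) and Bcl6 (-0.28) were below 0. The threshold had chosen these 19, so a test on them is void and the rise is given as an observation. Whether FoxO activity changed was not tested.

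The small fall of the cell-cycle lists may reflect differences between arrays that do not follow the knockdown. For G1/S and DNA replication, another split of the 6 arrays gave a median 1.36 times the size of the real one, and for G2/M and mitosis the highest other split reached 0.92 times. Those splits mix the days, and among the 3 other splits that part all 3 pairs the highest reached 0.6 and 0.63 times. The medians were below 0 in each pair, at -0.12, -0.115 and -0.179 for G1/S and -0.131, -0.104 and -0.323 for G2/M. Every such split also holds both groups on each side, so part of the knockdown difference enters its median. With so few splits, none of them free of that difference, the explanation stays open for both lists.

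Among the other lists called, the highest of all other splits reached 1.12 times the real median for ATF4, 0.99 for MAPK, 0.72 for cholesterol, 0.68 for glutathione, 0.62 for AP-1, 0.6 for interferon and 0.49 for astrocyte genes. Among the splits that part all 3 pairs, the highest were 0.61 for ATF4, 0.45 for MAPK, 0.55 for cholesterol, 0.67 for glutathione, 0.39 for AP-1, 0.47 for interferon and 0.49 for astrocyte genes. Part of the knockdown difference enters all these values, so they do not measure differences between arrays alone.

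The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share below 0.05. Every split other than the real one holds control and knockdown arrays on both sides. It carries part of the knockdown difference and puts the rest into the spread. Counts of genes near 0 there follow in large part from the design, so these splits are not a null. The real split gave 1048 genes past the threshold, 360 of them changed at least 2-fold, and the highest of the other splits gave 0 and 0, so that 1 split reached each count. For gene lists, 1 split reached the 9 lists of the real one and the highest other gave 7. Among the 4 splits that part all 3 pairs, the 3 others gave 0 genes and 0 to 6 lists.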
